A study of Mus musculus with 6 samples.

How the data were processed

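Thymic iNKT cells of wild-type and Prkd2/3-deficient mice were profiled by single-cell RNA-seq, single-cell TCR-seq and single-cell ATAC-seq, with 1 library for each of 2 genotypes and 3 assays, 6 libraries in all. Per the labels' protocols, cells were enriched magnetically and sorted as TCR beta-positive, CD1d tetramer-positive and propidium iodide-negative. Expression and receptor libraries were made with the 10x Genomics 5′ and V(D)J kits, and nuclei of purified cells were used for chromatin. The genotype of each library was taken from its title. The labels give no strain, sex, age or number of animals. The wild-type expression library held 57879346 UMIs in 9641 barcodes and the deficient one 45213370 UMIs in 6274 barcodes, with 33696 features each.

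The deposited expression values are UMI counts per gene and cell, made with Cell Ranger 8.0.1 per the file headers and limited to the barcodes that the program called as cells. The deposited TCR tables give counts of UMIs and reads per assembled chain and counts of cells per clonotype. They also give the deposited proportion (fraction) of each clonotype, its cells over all cells with a clonotype. These tables hold productive chains of called cells, as checked on their values, and Cell Ranger is named for them per the submitters' processing notes. The peak tables list regions called per library, with the gene, the distance and a promoter, distal or intergenic type for each. Cell Ranger ATAC 1.2.0 is named for these per the submitters' processing notes. They hold no height or p-value, so the depth of the chromatin libraries is not given in the sources used here. The notes name mm10, GRCm38 and GRCm39 without saying which applies to which assay. Peak positions were therefore compared with the RefSeq genes of GRCm38: 8835 of 10261 wild-type and 9193 of 10725 deficient promoter peaks with a single gene lay within 2000 bp of an end of that gene.

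Cells with at least 500 genes and under 10% mitochondrial UMIs were kept, which removed 199 wild-type and 81 deficient barcodes. Doublets were scored with the Scrublet procedure, rewritten with exact neighbours, and the highest scores were removed at 0.8% per 1000 barcodes (744 and 315 cells). This left 8709 and 5878 cells with 51193157 and 40903036 UMIs. For clustering, UMIs were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without TCR, immunoglobulin, ribosomal, mitochondrial and sex-linked genes, went into 30 principal components of both libraries together. A shared-neighbour graph (20 neighbours) was clustered with the Leiden method at resolution 1. Clusters were named after clustering, from marker lists fixed beforehand: the name came from the list with the highest mean score or with most members among the 10 leading genes. Clusters 4, 10 and 11 had low depth and at most 1 listed marker among their 10 leading genes. They were pooled as unnamed low-depth cells, although their highest mean scores were for NKT1-like, cycling and stage 0-like markers. Clusters 7 and 13 kept their numbers, although their highest mean scores were for B cell-like and myeloid cell-like markers.

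Expression was summed over all kept cells of a library, or over the cells of a class, and divided by the summed UMIs to give CPM. For list medians, the ranking of genes and the alternatives for named genes, a library with 0 UMIs of a gene was set to a floor of 3 UMIs. Intervals are exact 95% Poisson intervals for CPM, exact conditional intervals for ratios and exact binomial intervals for shares, and all describe counting error in these libraries. With 1 library per group no test between the genotypes, p-value or number of changed genes was computed. Classes were to be compared where both libraries held at least 200 cells, which among the named classes only NKT1-like cells met, and NKT17-like cells were added after seeing the data. The 22 gene lists were fixed before the data were examined, as were the gene rules, the settings and the first set of alternatives. Members of at least 5 CPM on average entered a list's median log2 ratio, which was placed among 10000 random lists matched on size and expression, and members at least 1.5-fold apart were counted. Of 374 symbols in all lists, 5 were not among the features: Cd163l1, Tcrg-C1, Tcrg-C2, Tcrg-C4 and Tcrg-V6.

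The genes named in the text were the 12 highest and 12 lowest ratios among genes of at least 20 CPM across all cells, and the 8 highest and 8 lowest of at least 50 CPM within a class. Up to 4 members per gene list and the genes Prkd1 to Prkd3, Zbtb16, Tbx21, Gata3, Egr2, Ifng, Il4 and Il17a were added to these, and 1 further gene of this rule is not reported here. Genes named for cluster 7, cluster 13, the thymocyte markers and single loci outside this rule were chosen after their values were seen. Across 5918 genes of at least 20 CPM the median log2 ratio was -0.01, and no scaling moved it past -0.05. The central 90% of these ratios reached from -0.64 to 0.69. Members of the Klra, Klr and H2 gene families have near-identical copies, so their counts are uncertain where the counting could split them.

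A canonical alpha chain was TRAV11 or TRAV11D joined to TRAJ18. TRBV use was counted over cells with exactly 1 productive TRB chain, for genes of at least 2% of cells. Most TRBV13-2 calls also named TRBV12-2 (4039 against 177 without it in the wild-type, 2833 against 116 in the deficient library) and were counted as TRBV13-2. A clone was a set of cells with the same TRBV gene and CDR3 nucleotide sequence of the TRB chain, and both libraries were thinned to the same number of cells 100 times. Peaks shared at least 1 bp to count as overlapping, and peaks per gene followed the deposited annotation, with random lists as for expression.

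Fold ratios, gene lists, a peak list and clone thinning were tested on simulated data, and the other steps were not. For folds and gene lists, both libraries were drawn as Poisson counts from the same pooled expression profile. Coverage near 95% was thus built in, and spread between cells, clones or animals was not simulated. With 200 genes changed among 5932 across all cells, true folds of 1.5, 2 and 4 gave medians of 1.496, 2.004 and 3.99, and 92.6 to 95.5% of intervals covered the truth. Of 100 unchanged lists, 5 lay outside the central 95%. Among 2749 genes of NKT1-like cells the medians were 1.502, 2.01 and 3.98, and 7 of 100 unchanged lists lay outside. Among 2799 genes of NKT17-like cells they were 1.46, 1.99 and 4.005, with 2 of 100 lists outside. A simulated peak list raised 2-fold, over other genes that were themselves slightly higher in the same group, came back at a median log2 ratio of 1.22. Clone thinning returned 58.28% where 58.33% was true.

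Alternatives covered the cell filter, doublet removal, clustering resolution, marker counts in place of clusters, number of variable genes, projection on the wild-type library, centring per library, depth, scaling, class make-up, list filters, clone definition and peak type. Analyses ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, with bedtools 2.31.1 for peaks. Accessibility per cell was not analysed here.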

Results

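Invariant natural killer T (iNKT) cells are T cells with a semi-invariant receptor for lipids presented by CD1d. They were purified from the thymus of wild-type mice and of mice lacking Prkd2 and Prkd3, which encode serine/threonine kinases of the protein kinase D (PKD) family. Single-cell RNA-seq, TCR-seq and ATAC-seq gave 6 libraries, 1 per genotype and assay. No difference between the genotypes therefore has a replicate check, and all intervals below are 95% intervals that cover counting error only. The labels give neither the strain, sex and age of the animals nor how many contributed to a library. The wild-type expression library held 57879346 UMIs in 9641 cell barcodes, with a median of 5116 per barcode. The Prkd2/3-deficient one (called the deficient library) held 45213370 UMIs in 6274 barcodes, with a median of 6651. After filtering, 8709 wild-type and 5878 deficient cells were compared, with medians of 5048 and 6550.5 UMIs. TCR chains were read in 8463 wild-type and 5738 deficient cells. The chromatin libraries are described here by their lists of 90421 and 102617 peaks, whose depth is not given in the tables used.

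Summed over all kept cells, transcripts of both targeted genes were lower in the deficient library, which does not show that every class had less. Prkd2 (ENSMUSG00000041187) had 61.6 CPM (UMI counts scaled to the library total) in the wild-type and 32.0 in the deficient library, 1.92-fold lower (1.80 to 2.05). Prkd3 (ENSMUSG00000024070) had 69.9 and 25.4 CPM, 2.75-fold lower (2.56 to 2.95). Within NKT1-like cells (defined with the classes), Prkd2 had 63.3 and 27.4 CPM and Prkd3 70.2 and 29.6 CPM. Prkd1, the remaining family member, had 2 UMIs in the wild-type and 0 in the deficient library. The 5′ tags counted here can lie outside the deleted part of a gene, so the UMIs left in the deficient library check nothing. Of 16 measured genes of PKD signalling, none was at least 1.5-fold higher and 4 were at least 1.5-fold lower, with a median log2 ratio of -0.28. The other 2 were Hdac7 and Hdac5, which encode class IIa histone deacetylases known as PKD substrates. Hdac7 had 56.6 and 24.5 CPM, and Hdac5 30.8 and 18.8 CPM.

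The make-up of the iNKT compartment, the question of the first comparison, differed widely between the libraries. NKT17-like cells, which express Il23r, Blk and Serpinb1a, made up 1.37% of wild-type cells (119 cells; 1.13 to 1.63) and 41.1% of deficient cells (2416 cells; 39.8 to 42.4). NKT1-like cells, which express Tbx21, Ifng and natural killer receptors, made up 67.9% (66.9 to 68.9) and 29.98% (28.8 to 31.2). NKT2-like cells, a class led by Il4, Il13 and Plac8 over both libraries together, made up 8.59% (8.01 to 9.20) and 1.02% (0.780 to 1.31). The 60 deficient cells of this class differed from that description, with Plac8 at 247 CPM in wild-type and 7.59 in deficient cells, Il4 at 232 and 34.2 and Il23r at 31.8 and 154. These 3 genes were chosen after their values were seen. Stage 0-like cells, marked by the early thymic genes Itm2a, Sox4 and Lef1, made up 0.632% (0.476 to 0.821) and 6.77% (6.14 to 7.44). A further group, cluster 7, held 10 wild-type cells (0.115%; 0.0551 to 0.211) and 711 deficient cells (12.1%; 11.3 to 12.96). Its listed markers among the leading genes split between stage 0 and NKT2 markers (Sox4, Ccr9, Slamf6). By mean score it stood highest for B cell-like markers (1.24), then for stage 0-like (1.12) and NKT2-like ones (0.79). Since the markers disagree and nearly all of its cells come from 1 library, cluster 7 is given no type name. Its share ratio of 105 came to 1.63 on projection of deficient cells on the wild-type library, and other settings gave 26.1 to 395.

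Fewer deficient cells carried an interferon programme led by Ifit3, Ifit1 and Isg15: 7.31% of wild-type (6.78 to 7.88) and 2.84% of deficient cells (2.43 to 3.30). This class pools cluster 6, with 7.29% and 1.75% of cells, and the small cluster 12, which went the other way. Cluster 12 held 2 wild-type and 64 deficient cells (0.0230% and 1.09%) and carried NKT17 genes (Il23r at 242 and Serpinb1a at 462 CPM). Cycling cells made up 2.81% (2.48 to 3.18) and 1.74% (1.42 to 2.103). Low-depth cells left unnamed made up 11.3% (10.6 to 11.9) and 3.56% (3.10 to 4.06). Of these, cluster 4 held 10.3% and 1.12% and cluster 10 0.976% and 0.902%, while cluster 11 went the other way, with 0.0344% and 1.53%. By mean score, cluster 4 stood highest for NKT1-like (0.70), cluster 10 for cycling (0.92) and cluster 11 for stage 0-like markers (1.05). The shares given for those classes leave these cells out. Cluster 13, with MHC class II and Cd209 transcripts, held 1 wild-type and 53 deficient cells (0.902%; 0.676 to 1.18), of which 8 had a TCR chain. The deficient share of NKT17-like cells was 30.1 times the wild-type share (25.02 to 36.5) in the chosen clustering. Of 13 other treatments of the cells, 8 gave ratios of 15.4 to 24.2 and 5 gave 27.9 to 33. Without clusters, counting cells with at least 2 or at least 3 of the markers Il23r, Ccr6, Il17re and Blk gave lower ratios, 12.6 (10.98 to 14.5) and 12.3 (10.3 to 14.7). This count was chosen after seeing the data. Of 226 wild-type cells with at least 2 of these markers, 113 lay in the NKT17-like and 96 in the NKT2-like class. Of the 60 deficient NKT2-like cells 36 had at least 2 of them, so the deficient share of that class does not count NKT2 cells alone. The NKT2-like share reversed, to 2.19 times the wild-type share, when deficient cells were assigned to wild-type classes by their nearest wild-type cells.

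**Figure D1:**
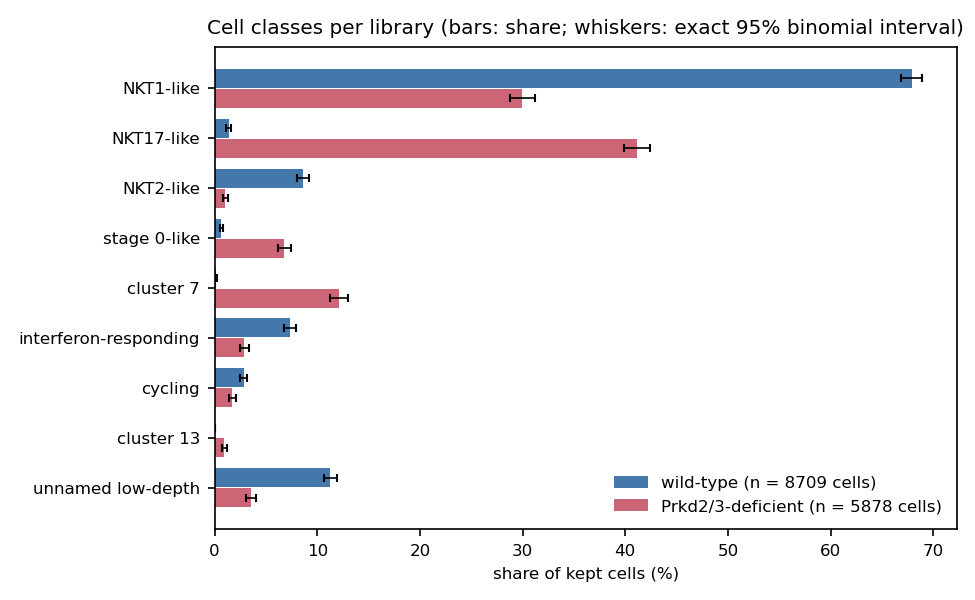
Share of kept cells (%) per class in the wild-type (8709 cells) and Prkd2/3-deficient (5878 cells) libraries; whiskers are exact 95% binomial intervals. NKT1-like cells hold 67.9% and 29.98%, and NKT17-like cells 1.37% and 41.1%.

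Across all kept cells, the 12 genes of at least 20 CPM furthest higher in the deficient library included MHC class II genes. Among them were Cd8a (0.566 and 173 CPM in the wild-type and deficient library), Fxyd7 (0.352 and 55.5), Lag3, an inhibitory receptor for MHC class II (3.56 and 102), Mmp25 (2.72 and 69.4) and Il22, a cytokine of type 17 lymphocytes (5.27 and 127). With both libraries weighted to the same shares of the 6 named classes, without other cells, the log2 ratio of Il22 came from 4.59 to 0.58, Mmp25 from 4.67 to 0.68, Fxyd7 from 7.30 to 3.07, Lag3 from 4.85 to 3.94 and Cd8a from 8.25 to 6.15. H2-Aa (0.273 and 342 CPM), H2-Eb1 (0.234 and 223), H2-Ab1 (0.293 and 192), H2-DMb1 (0.469 and 40.5), Cd74 (6.76 and 1054) and the lectin gene Cd209d (0.137 and 70.0) came mostly from the 53 cells of cluster 13. Without that cluster, an alternative chosen after seeing the data, their deficient values were 4.65 (H2-Aa), 3.80 (H2-Eb1), 2.40 (H2-Ab1), 0.974 (H2-DMb1), 27.0 (Cd74) and 0.150 CPM (Cd209d). Cd8a then kept 169.9 CPM, Lag3 92.2 and Il22 129.6, and the NKT17 genes Serpinb1a, Tmem176b and Tmem176a joined the 12 highest. Jchain, whose product joins immunoglobulin polymers, had 0.195 and 102 CPM. It turned lower in the deficient library with both libraries weighted to the same class shares (log2 ratio -0.55). For Cd209d this setting gave -0.25, but that sign comes from the floor of 3 UMIs. Outside cluster 13, Cd209d had 0 wild-type and 6 deficient UMIs, so no lower level is drawn from it. Jchain is among the leading genes of cluster 7.

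The 12 genes of at least 20 CPM furthest lower in the deficient library included granzyme and Ly49 receptor genes. Gzma, which encodes granzyme A, had 248 CPM in the wild-type and 1.59 in the deficient library, 156-fold lower (122 to 202). Gzmb had 294 and 10.6 CPM. The Ly49 receptor genes Klra9 and Klra3 had 371 and 11.03, and 138 and 11.1 CPM. Il12rb2, a subunit of the IL-12 receptor, had 219.6 and 24.4 CPM, and Zfp683, which encodes the residency factor Hobit, 51.5 and 7.31. The others among the 12 lowest were Styk1 (163 and 4.38), Cd40lg (166 and 22.9), Arsb (161 and 19.5), Atp8a2 (66.7 and 5.62), Ifitm3 (53.4 and 6.28) and ENSMUSG00000121360, listed without a symbol (150.1 and 3.25). With both libraries weighted to the same class shares all 12 stayed at least 2-fold lower, but the log2 ratio of Gzma came from -7.28 to -6.18, Klra3 from -3.64 to -2.50, Il12rb2 from -3.17 to -1.91 and Zfp683 from -2.82 to -1.59.

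Tbx21, which encodes the type 1 factor T-bet, had 102 and 36.3 CPM, 2.805-fold lower in the deficient library (2.65 to 2.97). Zbtb16, which encodes the iNKT factor PLZF, had 314 and 269 CPM, Gata3 119.8 and 87.0, and Egr2 9.02 and 14.9. Among cytokines, Il17a had 8.11 and 57.7 CPM, Ifng 149 and 68.4, Il4 89.8 and 13.7, and Il13 26.5 and 0.856.

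Gene lists fixed in advance are given as the median log2 ratio of their measured members, deficient over wild type, beside 10000 random lists of the same size and expression. NKT17 genes had the highest median, 3.11 (-0.03 with both libraries weighted to the same shares of the named classes, without other cells, called equal class shares from here on), with 14 of 17 members at least 1.5-fold higher and 0 lower, among them Serpinb1a (12.8 and 295 CPM) and Ltb4r1 (3.54 and 52.5). Stage 0 genes had a median of 0.85 (-0.03 at equal class shares), with 9 of 14 higher, such as Cd24a (0.899 and 10.0) and Sox4 (9.65 and 75.6), and 2 lower, among them Satb1 (329.7 and 98.4). NK receptor genes had a median of -1.60 (10 of 14 lower, 2 higher; -0.65 at equal class shares), NKT1 effector genes -0.87 (16 of 22 lower, 1 higher; -0.08 at equal class shares) and NKT2 genes -0.46 (6 of 15 lower, 3 higher). Interferon response genes had a median of -0.57 (9 of 20 lower; 0.07 at equal class shares), with Ifi27l2a at 649 and 284 CPM, and proliferation genes -0.39 (10 of 22 lower; 0.25 at equal class shares). All of these lay outside the central 95% of random lists.

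Further lists had higher medians in the deficient library, most of them by less at equal class shares. In several of them members went both ways. Checkpoint receptors had a median of 0.72 (3 of 6 higher, 1 lower; 0.38 at equal class shares), with Pdcd1 at 47.6 and 212 CPM and Tox at 216 and 466. This median came to 2.15 with members of at least 20 CPM and to 0.34 with members of at least 1 CPM. TCR-induced genes had a median of 0.37 (6 of 17 higher, 4 lower), with Cd69 at 193 and 463 CPM and Egr1 at 54.2 and 131. NF-kB genes had a median of 0.39 (5 of 13 higher), led by Bcl3 (17.4 and 57.7). Genes induced by tissue dissociation and stress were higher too, with a median of 0.70 (9 of 16 higher, 0 lower; 0.44 at equal class shares), Jun at 225 and 693 CPM and Hspa1a at 2.01 and 18.6. CD3 and TCR genes had a median of 0.63 (5 of 10 higher, 1 lower; 0.28 at equal class shares), with Cd8b1 at 1.70 and 38.7 and Cd4 at 39.8 and 18.2. SLAM-SAP genes had 0.54 (3 of 8 higher, 1 lower; 0.16 at equal class shares), with Slamf6, a receptor needed for iNKT selection, at 30.7 and 86.4. Cytokines had 0.53 (5 of 11 higher, 4 lower) and egress and residency genes 0.43 (3 of 13 higher, 1 lower), which came to 0.30 and 0.15 at equal class shares.

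The remaining lists lay within the central 95% of random lists across all kept cells. These were lineage transcription factors (0.12; 10 of 27 higher, 6 lower), glycolysis (0.09; 2 of 15 higher, 2 lower), cytokine receptor and STAT genes (0.08; 4 of 21 higher, 5 lower), oxidative phosphorylation (0.04; 0 of 21 either way), MHC and antigen presentation (-0.02; 1 of 12 higher) and survival and apoptosis genes (-0.11; 1 of 16 higher, 3 lower). Among their members, the proapoptotic gene Pmaip1 had 3.44 and 14.96 CPM and Il2ra, the high-affinity IL-2 receptor chain, 4.67 and 33.3 CPM. Lineage factors included Myb at 10.98 and 41.6 and Zbtb7b at 41.4 and 14.0. The last encodes ThPOK, known as a repressor of CD8 genes.

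**Figure D2:**
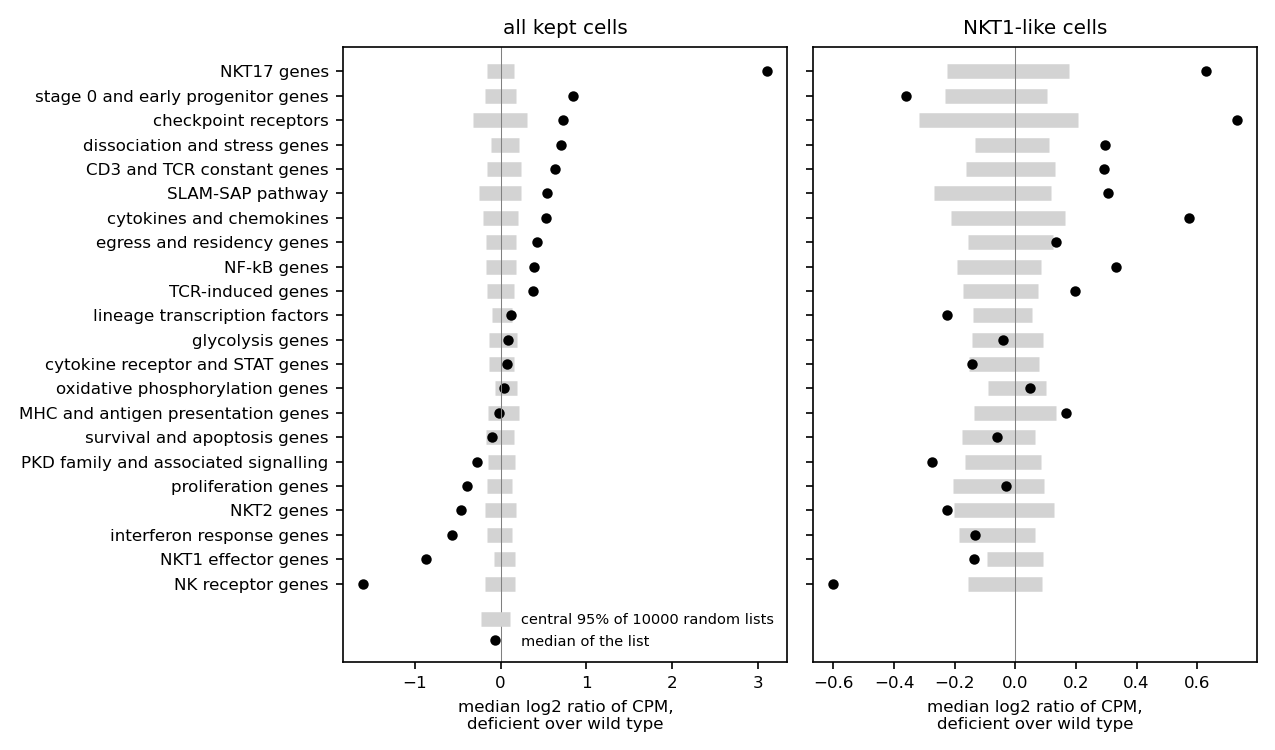
Median log2 ratio of CPM, deficient over wild type, of the 22 gene lists for all kept cells and for NKT1-like cells (points), with the central 95% of 10000 random lists matched on size and expression (grey bars). Across all cells NKT17 genes lie at 3.11 (-0.03 at equal class shares) and NK receptor genes at -1.60 (-0.65 at equal class shares); within NKT1-like cells the medians span -0.60 to 0.73.

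Within a class, the second comparison asked which levels differed apart from class make-up. NKT1-like cells of the deficient library expressed Cd8a (ENSMUSG00000053977), which encodes the CD8 alpha chain, at 304 CPM against 0.258 in wild-type cells. Of the deficient NKT1-like cells, 66.8% had a Cd8a UMI (1177 of 1762; 64.5 to 69.0), against 0.118% of wild-type ones (7 of 5913; 0.0476 to 0.244), at median depths of 6125 and 5051 UMIs. Stage 0-like cells of the deficient library, with a median of 4338 UMIs, gave 13.1% (9.91 to 16.8). With every cell thinned to 2000 UMIs the shares were 38.6% in deficient and 0.0689% in wild-type NKT1-like cells, and 8.68% in deficient stage 0-like cells. Cd8b1 had 0.936 and 47.0 CPM and Cd4 26.3 and 10.5 CPM. The class holds mostly different clusters in the 2 libraries: 3015 and 2895 of its 5913 wild-type cells lay in clusters 0 and 1, and 1715 of its 1762 deficient cells in cluster 3.

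The other genes furthest higher in deficient NKT1-like cells were Lag3 (1.097 and 136 CPM; 124-fold, 88.5 to 180), the lectin-like receptor gene Klrh1 (1.61 and 111), Emb (3.16 and 148), Eng (3.13 and 129), Itga4, the alpha 4 integrin chain (21.4 and 492), Ptms (25.6 and 212) and Lmna (18.5 and 116). Lowest were Gzma (331 and 3.90 CPM; 84.9-fold lower, 63.2 to 117), Gzmb (379 and 22.0), Klra9 (516 and 34.1), Styk1 (174 and 12.8), Ly6a (222 and 17.03), Arsb (162 and 25.1), Cd40lg (176 and 28.4) and ENSMUSG00000121360 (197 and 10.0). Ifng had 203 and 208 CPM, 1.02-fold (0.976 to 1.07), and Tbx21 126 and 91.0 CPM, 1.38-fold lower (1.29 to 1.48). Il4 had 53.2 and 2.39 CPM. Zbtb16 had 167 and 146 CPM and Gata3 109 and 91.2. Il17a had 4 UMIs in the wild-type and 1 in the deficient cells, and Egr2 6.26 and 4.88 CPM with a fold of 0.779 (0.567 to 1.06).

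By list, NK receptor genes kept the lowest median within NKT1-like cells, -0.60, with 8 of 14 lower but 4 higher, among them Klrc1, an inhibitory NKG2 chain (103 and 359 CPM). NKT1 effector genes split, with a median of -0.14, 7 of 22 lower such as Il12rb2 (256 and 71.6) and 4 higher such as the chemokine gene Ccl5 (1004 and 3434). Lineage transcription factors had a median of -0.23 (6 of 24 lower, 4 higher): Hivep3 (26.0 and 4.08), Zbtb7b (43.8 and 8.34) and Runx1 (116 and 39.8) were lower and Tcf7, a factor of early and memory-like T cells, was higher (69.7 and 234). Checkpoint receptors had 0.73 (3 of 6 higher), NKT17 genes 0.63 (4 of 7 higher, led by Serpinb1a at 1.90 and 18.4) and cytokines 0.57 (5 of 10 higher, 1 lower). Serpinb1a had 584 CPM in the NKT17-like cluster, which held 1.37% of wild-type and 41.1% of deficient cells. Free RNA in the droplets was not tested for the NKT17 genes, so their higher values here need not be levels within the class. Trafficking genes had a median of 0.13 (3 of 12 higher) and included S1pr1, the receptor that guides egress from the thymus (8.81 and 37.9), and Ccr7 (0.871 and 10.7). NF-kB genes had 0.33 (2 of 13 higher), CD3 and TCR genes 0.29 (2 of 10 higher), SLAM-SAP genes 0.31 (2 of 7 higher), MHC and antigen presentation genes 0.17 (1 of 12 higher) and TCR-induced genes 0.20 (5 of 17 higher, 3 lower), among them Nr4a2 (38.8 and 151). Dissociation and stress genes stood at 0.29 in the same cells (6 of 16 higher, 0 lower). PKD signalling genes had -0.28 (5 of 16 lower), stage 0 genes -0.36 (5 of 11 lower, 4 higher) and NKT2 genes -0.23 (4 of 10 lower, 3 higher). Proliferation genes stood at -0.03, within the random range, with 0 of 12 members 1.5-fold apart. Survival (-0.06), glycolysis (-0.04), oxidative phosphorylation (0.05), interferon (-0.13) and cytokine receptor genes (-0.14) also lay within it.

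NKT17-like cells were compared although the wild-type library held only 119 of them, a choice made after seeing the data. Several NKT17 markers stood lower or close in deficient cells. Il23r had 387 and 364 CPM, Il17a 187 and 119.8, Ccr6 158 and 103 and Blk, a Src-family kinase, 599 and 308. Il22, the leading gene of the class, was higher at 195 and 263 CPM, as was Fxyd7, also among its 10 leading genes. NKT17 genes had a median of -0.24, with 4 of 17 lower and 0 higher. Highest in deficient cells were Cd8a (6.15 and 99.7 CPM), Fxyd7 (15.4 and 113), Klrk1, which encodes NKG2D (18.4 and 111), Atf3 (31.8 and 116), Cd69 (109.6 and 399), H2-Q7 (62.5 and 209), Tagap (33.8 and 108) and Traf1 (28.7 and 86.4). Lowest were Lgals3, which encodes galectin-3 (777 and 25.2; 30.8-fold lower, 27.4 to 34.6), Stab2 (239 and 13.8), Chn2 (138 and 18.1), the costimulatory receptor gene Cd28 (126 and 19.1), Cd40lg (114 and 24.8), Id3 (168 and 54.8), Arl4c (86.0 and 28.7) and Trerf1 (108 and 40.0). Zbtb16 had 494 and 334 CPM and Gata3 125 and 71.6. Dissociation and stress genes had a median of 0.57 in these cells (8 of 16 higher), NF-kB genes 0.55 (6 of 13 higher), MHC and antigen presentation genes 0.41 (5 of 12 higher) and TCR-induced genes 0.21 (7 of 17 higher, 1 lower). Stage 0 genes had -0.65 (6 of 10 lower), NK receptor genes -1.04 (3 of 5 lower, 1 higher), PKD signalling genes -0.29 (5 of 16 lower) and lineage transcription factors -0.22 (7 of 27 lower, 2 higher). The NK receptor value rests on 5 members. Klra9 was seen in 6.72% of wild-type NKT17-like and 7.27% of wild-type stage 0-like cells, and in 0.0828% and 0.754% of deficient ones. Free RNA in the droplets was not tested for these genes.

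Of the double-positive thymocyte markers, deficient NKT1-like cells had 0 UMIs of Rag1, Rag2 and Ptcra and 3 of Dntt, beside 3432 of Cd8a and 530 of Cd8b1. The other listed markers had 3 (Arpp21), 8 (Aqp11), 157 (Cd1d1) and 242 UMIs (Rmnd5a). Over all kept deficient cells Rag1, Rag2, Ptcra and Dntt had only 17, 1, 8 and 71 UMIs, so their absence shows little. Summed over all kept cells, the whole list of thymocyte markers had 49.7 and 265 CPM, and conventional single-positive markers 647 and 244. Of the deficient sum of thymocyte markers, Cd8a made up 173 and Cd8b1 38.7 CPM. Gamma-delta T cell markers had 189.6 and 469 CPM, nearly all of it Trgv2, while Trdc, which encodes the constant region of the delta chain, had 0.0586 and 0.782. B cell markers had 151 and 1565 CPM, with Cd74 and H2-Aa of cluster 13 in front, and Igkc 0.0781 and 50.8. Myeloid markers had 138 and 395 CPM, with Cst3 at 116.5 and 296.

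**Figure D3:**
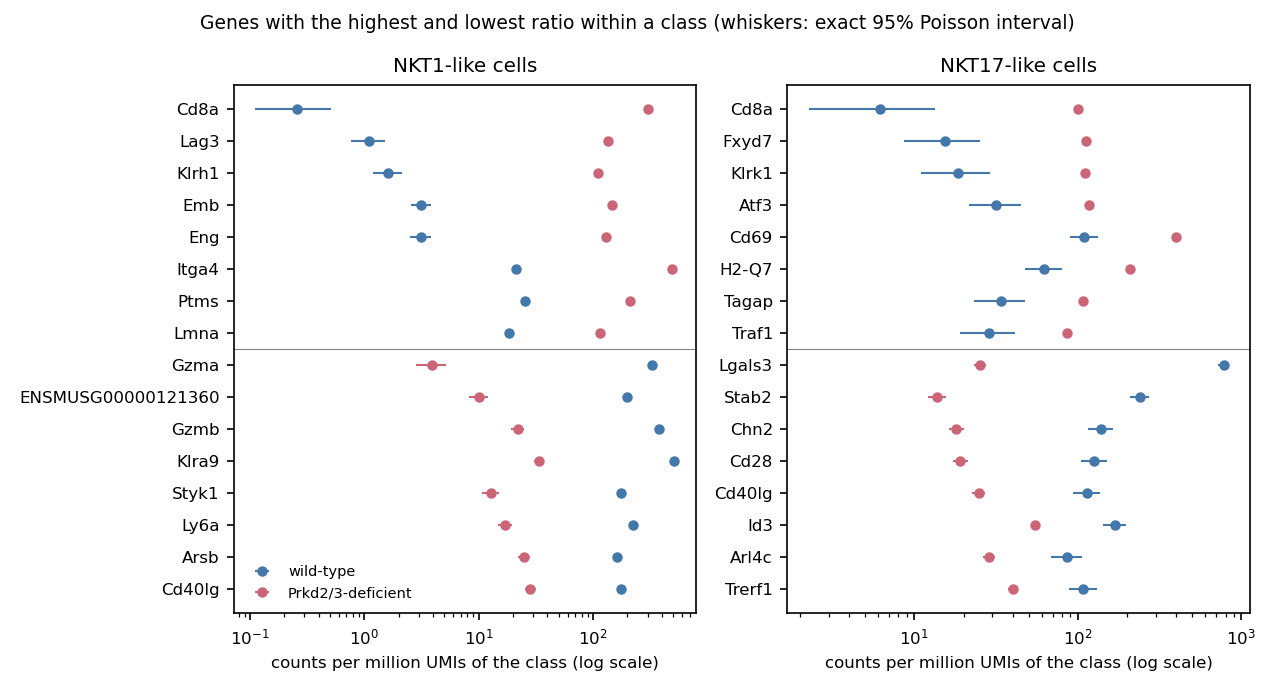
CPM (log scale) of the 8 genes with the highest and the 8 with the lowest ratio within NKT1-like and NKT17-like cells of each library; whiskers are exact 95% Poisson intervals. In NKT1-like cells Cd8a lies at 0.258 in the wild-type and 304 CPM in the deficient library, and Gzma at 331 and 3.90.

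Receptor sequences asked whether the sorted cells were iNKT cells in both libraries and how their clones were built. The canonical TRAV11-TRAJ18 alpha chain was found in 98.9% of wild-type (7615 of 7699; 98.7 to 99.1) and 97.8% of deficient cells with an alpha chain (5110 of 5225; 97.4 to 98.2). TRBV13-2 (V beta 8.2) was carried by 48.1% of wild-type and 49.4% of deficient cells (47.0 to 49.3 and 48.1 to 50.8). TRBV29 (V beta 7) was carried by 17.5% (16.7 to 18.4) and 21.05% (19.9 to 22.2), TRBV13-1 by 14.3% (13.5 to 15.1) and 11.8% (10.9 to 12.7), TRBV1 by 9.53% (8.88 to 10.2) and 9.23% (8.45 to 10.1), and TRBV13-3 by 6.84% (6.28 to 7.44) and 4.90% (4.32 to 5.52). Counted over distinct rearrangements, TRBV1 took 9.60% and 7.35%. NKT17-like cells carried TRBV13-1 in 27.4% of 113 wild-type cells (19.5 to 36.6) and 12.4% of 2107 deficient cells (11.01 to 13.9).

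Cells of the deficient library shared beta chain rearrangements more often. At 5126 cells per library, 15.8% of wild-type cells (14.8 to 16.6 over 100 draws) and 36.5% of deficient cells belonged to a clone of at least 2 cells, a ratio of 2.31. Before thinning the wild-type share was 21.2% of 7468 cells. Among NKT1-like cells, at 1570 per library, the shares were 6.32% (4.84 to 7.81 over draws) and 30.1%, a ratio of 4.75 that was added after seeing the data. Thinning splits clone mates here too: before it the wild-type share was 17.7% of 5115 cells. The size of the ratio 4.75 therefore depends on thinning, while the deficient share stood higher both before and after it. In NKT17-like cells the shares were 49.6% of 113 wild-type and 48.4% of 2107 deficient cells. Thinning the deficient cells to 113 left 12.7% (5.73 to 19.9 over draws), below the 49.6% of wild-type cells. It splits most clone mates, so no direction is drawn for this class. The largest clone held 12 cells in the wild-type and 72 cells in the deficient library, of which 67 were NKT17-like. Among the clonotypes as deposited the largest held 88 wild-type and 48 deficient cells. Those clonotypes cover all 8463 and 5738 cells with a TCR chain, also cells without exactly 1 TRB chain. With TRB and TRA together the largest clones held 11 and 48 cells, so the 88 cells do not show a larger TRB clone. By TRB alone, the 10 largest clones held 0.897% and 5.21% of cells. Since the labels give no number of animals, these shares also depend on how many mice were pooled.

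**Figure D4:**
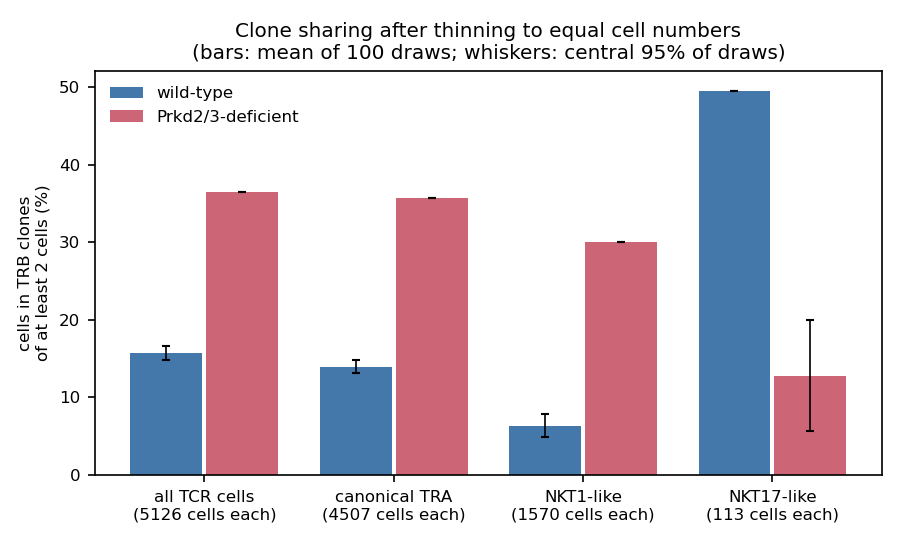
Percent of cells in TRB clones of at least 2 cells after thinning both libraries to the same number of cells; bars are means of 100 draws and whiskers the central 95% of draws. Deficient cells stand higher among all TCR cells (36.5% against 15.8%) and NKT1-like cells (30.1% against 6.32%). Before thinning these wild-type shares were 21.2% and 17.7%. In NKT17-like cells 2107 deficient cells were thinned to 113 and the wild-type ones not at all; before thinning the shares were 48.4% and 49.6%.

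Chromatin was compared as lists of accessible regions, each called in its own library, so a missing peak shows no change at that site by itself. The peaks were not divided by class, and class shares differed between the expression libraries. NKT17-like cells made up 1.37% of wild-type and 41.1% of deficient cells there, and stage 0-like cells 0.632% and 6.77%. Peak numbers can follow such a make-up, so a change within a class cannot be told apart from it. Of the wild-type peaks, 86.4% overlapped a deficient peak by at least 1 bp (86.1 to 86.6), and of the deficient peaks 78.0% overlapped a wild-type peak (77.7 to 78.2). Promoter peaks overlapped in 98.6% and 95.8% of cases and distal peaks in 84.3% and 75.6%. Peak widths had medians of 759 and 704 bp, and the lists covered 130.2 and 133 Mb.

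Cd8a had 2 wild-type and 14 deficient peaks and Cd8b1 1 and 7. A promoter peak at Cd8a (chromosome 6, 71371093 to 71377673, 6581 bp) was listed in the deficient library alone. Upstream, a deficient peak of 8500 bp (71350707 to 71359206) covered a wild-type peak of 354 bp (71357534 to 71357887). The peak tables name no build, and 86.1% of wild-type and 85.7% of deficient promoter peaks lay within 2000 bp of an end of their gene in the RefSeq annotation of GRCm38. Peaks at genes of double-positive thymocytes, the CD4+ CD8+ precursors, were listed in the deficient library alone at 3 loci: 3 at Rag1, 2 at Rag2 and 3 at Ptcra.

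**Figure D5:**
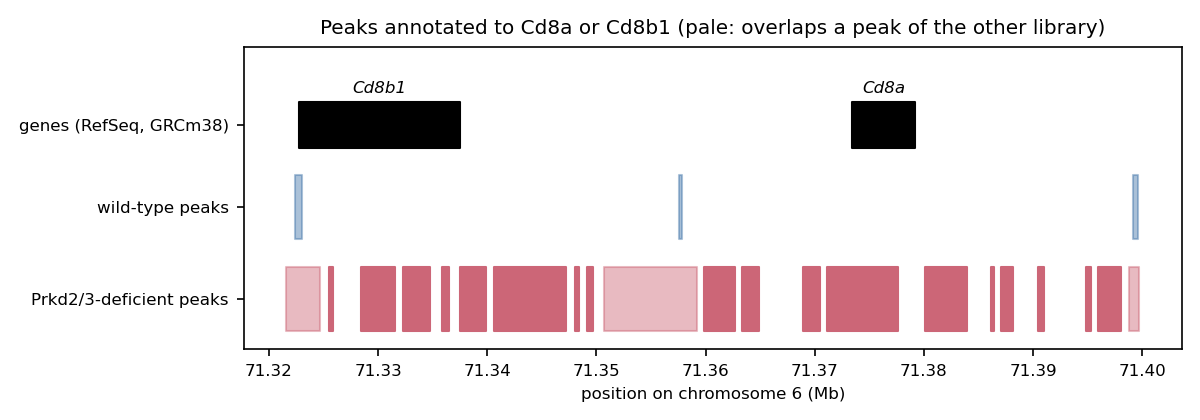
Peaks annotated to Cd8a or Cd8b1 on chromosome 6 (position in Mb) in each library, with the RefSeq gene bodies of GRCm38; pale boxes overlap a peak of the other library. Cd8a has 2 wild-type and 14 deficient peaks and Cd8b1 has 1 and 7.

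Il23r had 11 wild-type and 18 deficient peaks, Il22 2 and 7, Ccr6 9 and 13, and Il17a 6 and 9, whereas Blk had 11 and 10 and Ltb4r1 3 and 2. Promoter peaks at Il22 (chromosome 10, 118204327 to 118204958), Il23r (chromosome 6, 67488397 to 67493457) and Il17a (chromosome 1, 20730406 to 20731444) were listed in the deficient library alone. A larger share of NKT17-like cells cannot be told apart here from a change within such cells. Sox4 had 10 and 32, Myb 12 and 30 and Tox 43 and 100. Of the 5 Ly49 genes looked at, 4 had fewer deficient peaks, Klra5 10 and 1, Klra9 9 and 3, Klra1 11 and 7 and Klra3 6 and 4, while Klra7 had 3 and 3. Granzyme genes had Gzma 9 and 6 and Gzmb 15 and 12. Zbtb16 had 28 and 32, Tbx21 5 and 9, Gata3 21 and 27, Egr2 14 and 10, Ifng 33 and 40 and Il4 4 and 5. A higher number can come from wide peaks listed in pieces: the Tbx21 promoter peak spanned 15898 bp in the wild-type and 8115 bp in the deficient library. Prkd2 had 11 and 9 peaks and Prkd3 16 and 16, and each library listed distal peaks at both genes that no peak of the other library overlapped.

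By list, stage 0 genes had a median log2 ratio of peak numbers of 0.39, above the central 95% of matched random lists (-0.04 to 0.35), with 9 of 14 genes having more deficient peaks. Egress and residency genes, at -0.03, lay just below theirs (-0.03 to 0.35), with 7 of 14 having fewer. By median, the other 20 lists lay within theirs. NK receptor genes had a median of 0 with 91 wild-type and 77 deficient peaks, and NKT17 genes 0.19 with 143 and 177, 10 of 18 genes having more deficient peaks and 5 fewer. Medians of such counts often tie at 0, and means gave a different picture for some lists. By mean, NK receptor genes (-0.24, percentile 0.05) and interferon genes (-0.09, percentile 1.22) lay low among random lists, and CD3 and TCR genes high (0.49, percentile 99). Among distal peaks alone, the CD3 and TCR list, which also holds Cd4, Cd8a and Cd8b1, had a median of 0.58. That is at the upper limit of its range (-0.17 to 0.58). Over all peak types, Cd8a (2 and 14) and Cd8b1 (1 and 7) gained most in this list, and Cd247 fell (20 and 13). Interferon genes, at -0.13, lay below their distal range (0 to 0.34), as did MHC and antigen presentation genes at -0.11 (-0.10 to 0.42). Stage 0 genes stayed above theirs, at 0.42 (-0.03 to 0.37).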

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

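The tests of the Y-linked UMIs were all chosen after the result was seen. Sex-linked genes belong to no comparison of the report, and a signal appeared there: 208 barcodes of the deficient library had a UMI of Ddx3y, Eif2s3y, Kdm5d or Uty, which lie on the Y chromosome (3.32% of barcodes; 2.89 to 3.79). In the wild-type library 2 barcodes did (0.0207%; 0.00251 to 0.0749).

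Stray reads spread over all droplets are argued against, because 86.1% of these 208 barcodes (179) lacked Xist, the RNA of the inactive X chromosome, against 28.6% of all deficient barcodes. Cells of a male animal in a mostly female pool remain a candidate explanation. Of 12 clone mates of barcodes with Y-linked UMIs and no Xist, 3 had Xist (25%; 5.49 to 57.2), against 72.5% of 4967 other deficient cells. Clone mates here share a TRB rearrangement and need not come from the same animal, as 60 rearrangements occurred in both libraries, and 12 is a small number. The labels give neither sex nor number of animals, so the explanation stays open.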

How the results depend on the processing

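Chosen only after the results were seen were the clustering without genes 2-fold apart, the versions without cluster 13 or the unnamed low-depth cells, class shares over distinct rearrangements, the count of NKT17 markers in place of clusters, the NKT17-like class comparison and the clones of NKT1-like cells alone. Values below are deficient over wild type, with the reported value in brackets before an alternative.

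NKT17-like cells kept a higher deficient share (30.1) under every setting tried, but several roughly halved the ratio. It was 17.3 with at least 200 genes and under 20% mitochondrial UMIs, 15.4 with at least 1000 genes and under 5%, 17.3 with the automatic doublet threshold, 17.2 at resolution 0.5, 24.2 on projection on the wild-type library alone, 16.1 with each gene centred per library, 15.8 with cells thinned to 2000 UMIs and 16.7 without genes 2-fold apart within the NKT1-like class. With cells of at least 2 or at least 3 of 4 NKT17 markers in place of clusters it was 12.6 and 12.3. Of 226 wild-type cells with at least 2 markers, 96 lay in the NKT2-like class, so the ratio depends on where that class ends. Which cells changed class under each setting was not tested.

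NKT2-like cells (0.119) came to 0.088 with at least 1000 genes, 0.241 at resolution 0.5 and 0.076 with centring, and reversed to 2.19 on projection on the wild-type library alone. NKT1-like cells (0.442) came to 0.417 with at least 1000 genes and 0.41 without cluster 13 and unnamed low-depth cells. Cluster 7 (105) came to 228 and 395 with at least 200 and 1000 genes, 26.1 at resolution 0.5 and 1.63 on projection, so its ratio rests on the joint clustering. Stage 0-like cells (10.7) came to 16.6 on projection, and interferon-responding cells (0.388) to 0.547 at resolution 0.5 and 0.267 on projection. The other 67 of 90 alternatives for class shares stayed within the interval of the reported ratio. Stage 0-like and cycling cells gave no value at resolution 0.5, where no cluster took those names, nor did cluster 7 with centring (0 wild-type against 709 deficient cells).

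Giving both libraries the same class make-up took most lists toward 0: SLAM-SAP 0.157, stress 0.444, lineage transcription factors -0.049, NKT1 effector -0.083, NK receptor -0.651, cytokines 0.298, egress 0.15, checkpoint 0.379 and CD3 and TCR genes 0.277. MHC and antigen presentation genes came to 0.247. NKT17 genes (3.11) reversed to -0.03, stage 0 genes (0.85) to -0.031, proliferation genes (-0.39) to 0.248 and interferon genes (-0.57) to 0.074. Lineage transcription factors (0.12) and MHC genes (-0.02), within the random range across all cells, also changed sign. This setting gives the 6 named classes the same weights in both libraries. It also leaves out cluster 7, cluster 13 and the unnamed low-depth cells, so the move of a list belongs to both changes together. Its wild-type profile rests on 119 NKT17-like cells (weight 24.7%) and 55 stage 0-like cells (4.30%). Its deficient profile rests on 60 NKT2-like cells (5.59%), and no counting interval was computed for these values.

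With each cell scaled to the same total, stress genes came to 0.517, NKT1 effector genes to -1.05, NKT17 genes to 3.55, stage 0 genes to 1.31, cytokines to 0.306, proliferation genes to -0.094, oxidative phosphorylation to 0.181 and cytokine receptor and STAT genes to -0.145. In named iNKT classes only, NKT2 genes came to -1.15, stage 0 genes to 0.385 and cytokine receptor and STAT genes to 0.232. Members of at least 1 CPM gave 0.343 for checkpoint receptors, and members of at least 20 CPM gave 2.15 for them and -1.85 for NK receptors. Of the 24 genes named across all cells, 19 stayed at least 2-fold apart with the same class make-up. Jchain changed sign there, and Cd209d did so only through the floor of 3 UMIs. In named iNKT classes only, 20 stayed so, and Jchain changed sign. The other 5 alternatives kept all 24, and the 16 genes named in each class stayed 2-fold apart under all 3 alternatives tried. The other 170 of 198 values for lists stayed within their spread.

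Prkd2 (0.52) came to 0.454 and Prkd3 (0.364) to 0.416 with the same class make-up, and Prkd3 to 0.33 with each cell scaled to the same total. TRBV1 use came to 0.765 over distinct rearrangements, while 19 other TRBV values and all 4 alternatives of the canonical alpha chain stayed within their intervals. The clone ratio (2.31) came to 2.92 with TRB and TRA together, 2.56 with canonical TRA only and 4.75 in NKT1-like cells only.

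Peak overlap (86.4% and 78.0%) came to 69.3% and 61.0% with reciprocal overlap of at least 50%, 98.6% and 95.8% for promoter and 84.3% and 75.6% for distal peaks. Promoter peaks alone gave a median of 0 for TCR-induced, lineage transcription factor, NKT2, NKT17 and stage 0 genes. Distal peaks alone gave 0.16 for stress, 0.138 for proliferation and 0.585 for CD3 and TCR genes. The other 36 of 44 peak list values stayed within their spread, but those of promoter peaks could hardly differ from 0. No paired analysis was possible because each group has 1 library and no test was run.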

Other observations

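Cells of cluster 7 in the deficient library had 392 CPM of Sox4, 472 of Slamf6, 1710 of Izumo1r, which encodes folate receptor 4, and 338 of Zbtb16, beside 378 of the gut-homing receptor gene Ccr9 and 104 of the egress receptor gene S1pr1. Klf2, its activator, had 199 CPM there and 257 in deficient NKT1-like cells. These genes were chosen after their values were seen. Egr2, induced by receptor signals during selection, had 34.3 CPM there and 150.4 in deficient stage 0-like cells. Cd8a had 142, Cd8b1 75.5 and Cd4 102 CPM. Over both libraries cluster 7 also held markers of other cell types, with Igkc at 212 CPM (1384 in cluster 13 and at most 0.362 elsewhere), Cd74 at 157, H2-Aa at 33.02 and Cd79a at 23.1, so RNA or cells of other types in it are not excluded. A canonical alpha chain was found in 94.2% of these cells with an alpha chain (92.2 to 95.9).

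Stage 0-like cells of the wild-type and the deficient library had 382 and 640.2 CPM of Sox4, 528 and 1584 of Izumo1r, 299 and 141 of Zbtb16 and 86.4 and 113 of Cd24a, from 55 and 398 cells. Cd8a had 36.6 and 47.1 CPM in them. Cycling cells had 0 and 228 CPM of Cd8a, 98.4 and 7.09 of Il4 and 367 and 217 of Zbtb16. Beta chain junctions, which hold the CDR3 and the conserved residue at each end, averaged 14.2 and 13.9 amino acids (SD 1.48 and 1.52). Of 6594 and 3852 distinct TRB rearrangements, 60 occurred in both libraries.

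Of the tests on the NKT17-like share, the one on animals or libraries was chosen after the result was seen, as were all tests on Cd8a and on clone classes. The deficient share of NKT17-like cells was 30.1 times the wild-type share. Depth as the whole cause is argued against by a ratio of 15.8 (13.8 to 18.2) with each cell thinned to 2000 UMIs, a few expanded clones by 29.9 (23.7 to 38.3) over distinct rearrangements, and clusters set by genes that differ within a class by 16.7 (14.5 to 19.2) without such genes. A difference between the animals or libraries other than the genotype cannot be told apart from it, because there was 1 library per genotype.

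Cd8a had 304 CPM in deficient and 0.258 CPM in wild-type NKT1-like cells. Conventional CD8 or double-positive T cells in the sort are argued against by the canonical alpha chain in 98.3% of 1017 Cd8a-positive cells (97.3 to 99.02), beside 98.8% of 503 Cd8a-negative ones. Free RNA in the droplets would reach all classes alike, and Cd8a stood 6.46 times higher in deficient NKT1-like than in stage 0-like cells (5.20 to 8.12). Doublets with such T cells would carry a further beta chain, and 6.83% of 1113 Cd8a-positive cells had at least 2 TRB chains (5.42 to 8.47), beside 3.96% of 555 Cd8a-negative ones. Expression of CD8 by deficient iNKT cells thus remains a hypothesis that may hold for these libraries, found and tested on the same data and open to differences between the animals other than genotype.

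Clones may keep to a class. Of 532 deficient clones of at least 2 cells, 102 spanned at least 2 classes, against 294 to 330 when classes were shuffled among cells, which argues against random classes. In the wild-type library 31 of 486 did, against 130 to 148. Cells with the same rearrangement need not share an animal, as 60 rearrangements occurred in both libraries, and this pattern is a hypothesis only.

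Receptors of another unconventional lineage were rare. Evidence for the alpha chain of MAIT cells was listed for 1 wild-type (0.0118%) and 7 deficient cells (0.122%). Regulatory T cell markers summed to 317 and 390.1 CPM, epithelial or stromal ones to 24.0 and 41.6 and erythroid ones to 0.313 and 0.244.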
